A study of Mus musculus with 2 samples.

How the data were processed

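Periosteal cells of Prx1Cre;mTmG mice were measured by 10x single-cell RNA sequencing in 2 libraries, 1 from uninjured mice and 1 from mice at day 3 after tibial fracture, per the labels. The labels' protocols describe explant culture in medium with 20% serum and 10 ng/mL bFGF at 33 °C to 80% confluence, while the series' design text says that cells were used without expansion. The labels give the molecule as DNA, whereas the values are UMI counts of transcripts. All live cells were used and 20000 cells were loaded, per the labels' protocols. The deposited files hold counts, that is UMIs per gene and barcode, not normalized, per the file headers and the whole-number values. Cell Ranger, Seurat 4.0.1 and the build mm10 are named in the submitters' processing notes, and the matrix header gives software version 3.1.0. How barcodes were chosen as cells is not given in the sources used here. The annotation used for gene positions was that of GRCm38, which is mm10, and 30934 of 31055 feature identifiers were found in it; EGFP and tdTomato are features of the deposited files.

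Barcodes with fewer than 500 genes or 1000 UMIs were removed (69 uninjured and 1412 at day 3), then those with over 10% mitochondrial UMIs (73 and 457), which left 4431 and 14463. Doublets were scored with Scrublet in scanpy 1.11.5. Its automatic threshold marked only 4 and 2 cells, too few in both libraries. The highest scores were therefore removed at 0.8% per 1000 barcodes, which took out 163 and 1883 cells. The 4268 and 12580 retained cells were scaled to 10000 counts and log transformed. They were clustered together from 2000 variable genes chosen with the library as batch, 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 1 with seed 0, and no batch integration was run. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and edgeR 4.0.16, the last for TMM factors only.

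Clusters were named from 19 marker lists fixed before the data were examined, while the scoring rule was set after the clusters were seen. A cluster took the type with the highest mean marker score if at least 3 markers were detected, a marker counting as detected in at least 10% of the cells. It stayed unnamed if markers of another compartment exceeded 10% of their level in that compartment, if its 10 leading genes held more markers of another type, or if it was shallow with none of its markers among them. The threshold on other markers kept 15.1% of uninjured and 3.45% of day-3 cells out of the named classes, and the rule of 3 markers kept out a contractile cluster with 2.13% and 1.70%.

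UMIs were summed over the cells of a class and given as CPM of the class total, 56007598 UMIs in uninjured and 110482072 UMIs in day-3 mesenchymal-like cells. A ratio is CPM at day 3 over CPM in the uninjured library with an exact conditional binomial 95% interval. Shares of cells have exact Clopper-Pearson 95% intervals, and a count of 0 was given the limit that 3 counts allow. With 1 library per group no test, p-value or standard error was computed. Shares of cells with a UMI and the cycling share were computed after thinning each cell to 3000 UMIs, shallower cells being left out; a cell counted as cycling with at least 3 UMIs over 15 mitotic genes.

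The named genes were, by a rule fixed before the data were examined, the 15 highest and 15 lowest ratios among genes at 50 CPM or more in the higher library, the 2 highest and 2 lowest members of each of 27 fixed lists at 10 CPM or more, and 14 lineage and sex genes. Gene models without a proper symbol, mitochondrial, ribosomal and globin genes were left out of the 30 and only counted, 15 of the genes at least 2-fold higher and 21 of those at least 2-fold lower. Some examples of the lists are given in the text without their interval. A member of the fixed lists that the rule would name is not reported here. A list's median log2 ratio was given its percentile among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries.

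The ratio rule, the list percentiles and the thinning were tested on simulated data for the mesenchymal-like comparison. Apart from the changed genes, both simulated libraries were drawn from the same profile with counting error alone. Variation between animals, cultures or clusters was left out, so the results are not error rates for the real comparison. All 50 genes simulated 4-fold higher, 50 simulated 4-fold lower, 50 simulated 2.5-fold higher and 50 simulated 2.5-fold lower passed the 2-fold rule, and 0 of 2528 unchanged genes did, among 2728 genes. The counting intervals held the true ratio for 94.7% of 7607 genes, 6 of 200 random lists lay outside the central 95%, and the same cells thinned from different depths gave cycling shares of 38.4% and 35.6%, against 81.0% unthinned.

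Alternatives fixed before the data were examined were TMM scaling, equal weight per cell, all retained cells, every cell thinned to 3000 UMIs, no cycling cells, a minimum of 10 CPM, no minimum for list members, the mean in place of the median, at most 5% or 20% mitochondrial UMIs, no doublet removal, the automatic Scrublet threshold, libraries clustered apart, Leiden resolutions of 0.5 and 2, no thinning, thinning to 2000 UMIs and at least 2 mitotic UMIs. Alternatives added after the data were seen were male cells only, mixed clusters counted as mesenchymal-like, all clusters rich in EGFP together, and filters of 300 genes and 500 UMIs. Raw reads were not used here.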

Results

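Periosteal cells of Prx1Cre;mTmG mice, in which Cre activity switches a cell from membrane tdTomato to membrane EGFP, were profiled by droplet single-cell RNA sequencing after explant culture. There were 2 libraries, 1 from uninjured mice and 1 from mice at day 3 after a tibial fracture. The uninjured library held 4573 barcodes with 94034112 UMIs in all and a median of 19366 UMIs per barcode. The day-3 library held 16332 barcodes with 227191961 UMIs and a median of 7030. After filtering, 4268 and 12580 cells were kept, with medians of 19380.5 and 7452 UMIs. There were no replicates, so no test across samples was possible, and every interval below covers counting error only.

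The comparison addressed how periosteal cells respond to bone injury. Mesenchymal-like cells, named from fibroblast and skeletal progenitor markers, numbered 2096 in the uninjured library and 2906 at day 3. They held EGFP at 2575 and 1850 CPM, against 98.8 and 56.8 CPM in the macrophage-like cells of the same libraries. In the mesenchymal-like cells Bmp2, a bone morphogenetic protein needed for fracture repair, was at 111 CPM at day 3 against 2.55 CPM in the uninjured library, 43.3-fold higher (95% interval 36.7 to 51.4). Sema7a, a membrane-anchored semaphorin, was 68.5-fold higher at day 3 (52.8 to 90.5), Serpinb2, an inhibitor of plasminogen activators, 47.9-fold (43.6 to 52.7), and Mmp3, a matrix metalloproteinase, 43.9-fold (37.6 to 51.5). Mmp3 was uneven among the day-3 clusters, at 453 CPM in cluster 10, 47.2 CPM in cluster 3 and 8.55 CPM in cluster 6, against 5.74 and 0.496 CPM in the uninjured clusters 2 and 8. Fmod, a collagen-binding proteoglycan, was at 89.7 CPM in the uninjured library and 0.154 CPM at day 3, and Igf1, a growth factor for bone and muscle, at 101 and 1.08 CPM.

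Among 3212 genes at 50 CPM or more in the library where they were higher, 542 were at least 2-fold higher at day 3 and 220 at least 2-fold lower. With a minimum of 10 CPM the counts were 1411 and 522. The median log2 ratio of the 8143 genes at 10 CPM or more was 0.19. The uninjured mesenchymal-like cells lay in clusters 2 and 8, with 1155 and 940 cells, and those of day 3 in clusters 3, 6 and 10, with 1144, 1062 and 699 cells, so the ratios compare different clusters of the same named class. The day-3 library also held cells of both sexes and the uninjured library male cells, and the barcode sequences of the libraries came largely from different sets, although the labels name the same 10x kit for both.

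The gene with the highest ratio was Xist, the RNA that silences an X chromosome in female cells, at 0.0893 CPM in the uninjured library (5 UMIs) and 324 CPM at day 3. The cytokine Il11 was 23.3-fold higher at day 3 (7.43 and 173 CPM), the transcription factor Cebpb 22.2-fold (9.95 and 221 CPM), and the laminin receptor subunit Itga6 19.7-fold (11.4 and 225 CPM). The ERK phosphatase Dusp5 was 18.8-fold higher, the cystatin Cst6 18.1-fold, the uridine phosphorylase Upp1 16.4-fold, the pyrophosphate transporter Ank 15.8-fold (26.4 and 418 CPM) and the receptor-modifying protein Ramp3 14.6-fold. The calprotectin subunits S100a9 and S100a8 were 37.0-fold and 19.1-fold higher at 75.9 and 86.1 CPM, while the neutrophil-like cells of the same library held them at 49286 and 53954 CPM; without doublet removal the ratios were 13.5 and 7.11.

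At the other end, the cartilage and tendon matrix protein Comp had a ratio of 0.00325 (0.00206 to 0.00489; 64.0 and 0.208 CPM), the heparin-binding growth factor Ptn 0.00768 (206 and 1.58 CPM) and the matricellular protein Wisp2 0.0103 (467 and 4.81 CPM). The mitochondrial protein gene Ndufa4l2 had a ratio of 0.0168, the glutamate transporter Slc1a3 0.0194, the interleukin antagonist Il1rn 0.0227 and the receptor tyrosine kinase ligand Gas6 0.0356. Ptx3, a secreted pentraxin, had a ratio of 0.0405, Clec11a, a secreted osteogenic factor, 0.0476, and Cxcl12, a chemokine that retains haematopoietic cells, 0.0801. Ogn, a small proteoglycan, followed at 0.0904, the extracellular superoxide dismutase Sod3 at 0.0934 and the membrane protein Itm2a at 0.0987. The 30 named genes kept a 2-fold difference on the same side under the alternatives run. In male cells alone this held for 29, since Xist has no ratio there. Mmp3 was 19.7-fold higher in male cells and 88.8-fold with the libraries clustered apart. The sizes of the ratios depended on the setting. Without cycling cells 18 of the 30 moved by over 1.5 times, among them Sema7a at 128-fold, Serpinb2 at 108-fold and Bmp2 at 66.3-fold. With cells thinned to 3000 UMIs 7 did, with Sema7a at 478-fold and Igf1 at a ratio of 0.00464. Over all retained cells 8 did, with Igf1 at 0.455. With all clusters rich in EGFP 4 did, with Comp at 0.0290 and Fmod at 0.0125. The thinned values have no interval and rest on small counts. Even unthinned, Sema7a had 57 UMIs in the uninjured library and Igf1 119 at day 3, so counting error may account for those shifts. In GRCm38 coordinates, Sema7a (ENSMUSG00000038264) lies on chromosome 9 from 57940112 to 57962865, Serpinb2 on chromosome 1 from 107511423 to 107535478, Mmp3 on chromosome 9 from 7445822 to 7455975 and Bmp2 (ENSMUSG00000027358) on chromosome 2 from 133552159 to 133562885. Fmod (ENSMUSG00000041559) lies on chromosome 1 from 134037254 to 134048277, Comp on chromosome 8 from 70373558 to 70382066 and Igf1 on chromosome 10 from 87858265 to 87937042.

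Many of these genes differed in macrophage-like cells too. A gene was at a comparable level if its CPM in mesenchymal-like cells was at most 2 times that in macrophage-like cells, in both libraries. A gene that differed in mesenchymal-like cells alone could fail this rule. The rule therefore favours genes that differ alike and can raise the percents and the correlation below. Of 352 genes at least 2-fold higher at day 3 in mesenchymal-like cells and at a comparable level in macrophage-like cells, 322 (91.5%) were also at least 1.5-fold higher there, and of 88 genes at least 2-fold lower, 56 (63.6%) were also lower and 5 were higher. Of 1840 comparable genes under 2-fold apart in mesenchymal-like cells, 26.9% were at least 1.5-fold higher and 20.2% at least 1.5-fold lower in macrophage-like cells. With the macrophage-like ratios centred on their median, the percents were 84.4% and 75%, and 16.7% and 29.2% for the 1840 genes. Cebpb was higher in both classes, at 22.2-fold and 30.5-fold, while Igf1 and Gas6 had ratios of 0.760 and 1.01 in macrophage-like cells. Across 2280 genes, which are not independent replicates, the correlation of the log2 ratios in the classes was 0.748. In osteoclast-like cells, 303 of 326 comparable higher genes (92.9%) were also at least 1.5-fold higher and 1 was lower. Of 84 comparable lower genes, 53 (63.1%) were also lower there and 1 was higher. Among 1941 comparable genes under 2-fold apart, 17.9% were higher and 13.0% lower. The correlation over 2351 genes was 0.813.

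**Figure D1:**
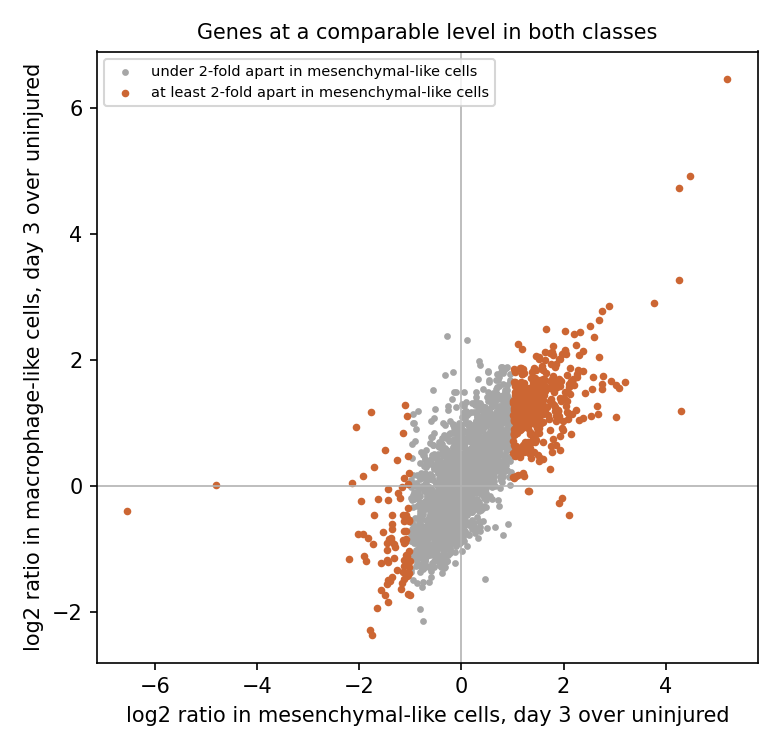
Log2 ratio, day 3 over uninjured, in macrophage-like cells against that in mesenchymal-like cells, a point for each of 2280 genes at a comparable level in both classes, orange where at least 2-fold apart in mesenchymal-like cells. The correlation across genes was 0.748, which the choice of comparable genes can raise, and Igf1 is the point farthest to the left at -6.54.

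**Figure D2:**
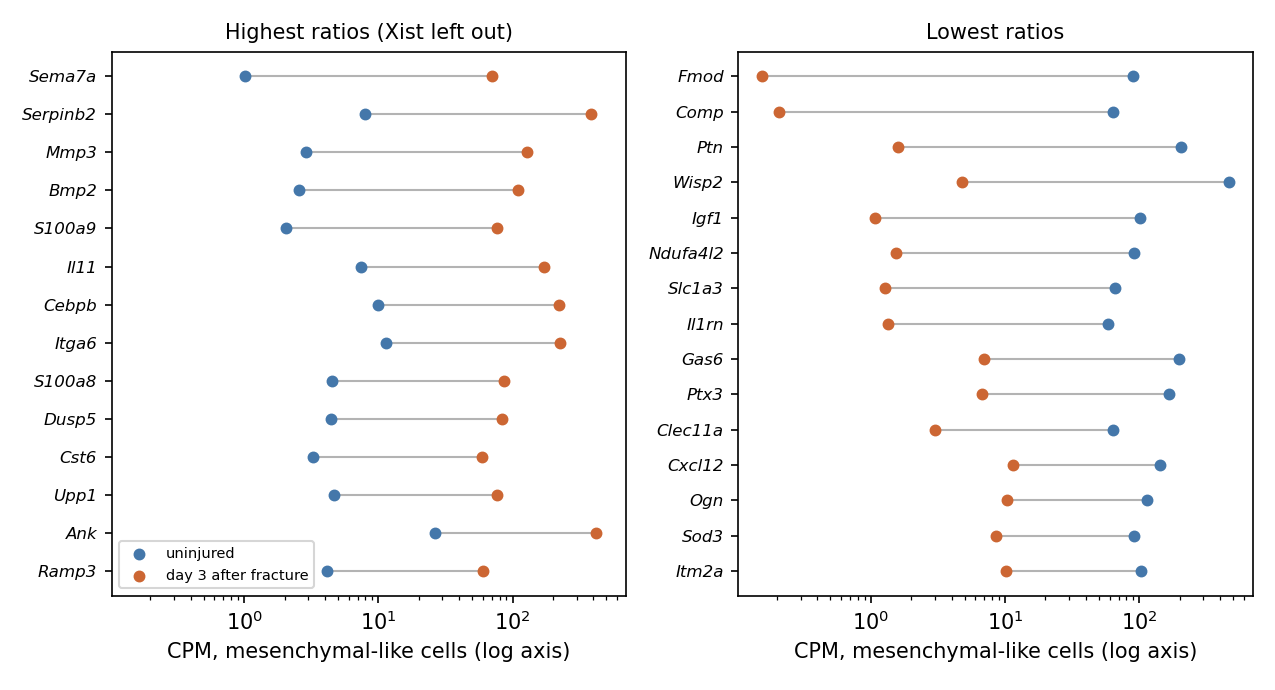
CPM of the named genes with the highest and lowest ratios in mesenchymal-like cells of the uninjured library (blue) and the day-3 library (orange) on a log axis, with Xist left out of the plot. Sema7a lies at 1.02 CPM in the uninjured library and 69.7 CPM at day 3, and Fmod at 89.7 and 0.154 CPM.

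Progenitor and lineage genes differed gene by gene. Prrx1, whose promoter drives the Cre, was 1.47-fold higher at day 3 (390 and 572 CPM), Cd34 1.91-fold (35.2 and 67.3 CPM) and the cartilage regulator Sox9 1.87-fold (72.3 and 135 CPM). Ly6a, which encodes the stem cell antigen Sca1, was at 621 CPM in the uninjured library and 212 CPM at day 3 (ratio 0.341), but at 505 CPM in day-3 cluster 10 against 149 and 94.9 CPM in clusters 3 and 6, and 877 and 403 CPM in the uninjured clusters. Cd34 was likewise uneven at day 3, at 147, 62.4 and 22.3 CPM in clusters 10, 3 and 6 against 44.7 and 27.2 CPM in the uninjured clusters. Of other genes with lower values at day 3, the smooth muscle actin gene Acta2 was at 1977 and 769 CPM (0.389), the matricellular gene Postn at 43.6 and 2.00 CPM (0.0459) and the alkaline phosphatase gene Alpl at 26.6 and 0.389 CPM (0.0147). Pdgfra (ratio 0.937) and the osteoblast regulator Runx2 (1.06) were at nearly the same level in both libraries, the osteoblast regulator Sp7 had a ratio of 0.585, and the cartilage genes Col2a1 and Acan had ratios of 0.671 and 0.489, Acan from 28 and 27 UMIs. When chondrocyte-like and contractile cells were added to the mesenchymal-like cells, the log2 ratios of Acan and Col2a1 were 2.39 and 0.48, and over all retained cells 2.12 and 0.39. Sp7 had a log2 ratio of 0.036 when the libraries were clustered apart, where osteoblast-like cells of the uninjured library formed a cluster of their own. In that setting Alpl had a ratio of 0.0425, and in male cells 0.00409.

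Shares of mesenchymal-like cells with a UMI, at 3000 UMIs per cell, were set beside the shares in macrophage-like cells as a gauge of background. Ly6a is an exception, since macrophage-like cells held it at 212 CPM at day 3, as mesenchymal-like cells did, so its share there is not background. The macrophage-like cells' median depths before thinning were 10280.5 and 4582 UMIs against 24617 and 34115 in mesenchymal-like cells. Prrx1 was seen in 65.8% of uninjured and 78.8% of day-3 mesenchymal-like cells (3.67% and 4.93% of macrophage-like cells), Cd34 in 9.99% and 17.0% (1.43% and 2.08%) and Sox9 in 18.7% and 31.8% (0.627% and 1.32%). The shares for Ly6a were 64.3% and 32.6% (13.7% and 27.5%), for Acta2 78.2% and 57.2% (30.9% and 11.7%), for Postn 11.3% and 0.558% (0.806% and 0.0216%), for Sp7 4.87% and 3.38% (0.0896% and 0.130%) and for Col2a1 2.01% and 1.15% (0.269% and 0.0865%). Alpl was seen in 6.31% of uninjured and 0.0698% of day-3 mesenchymal-like cells, against 0.269% of uninjured macrophage-like cells and 0 of 4623 at day 3, which allows a share of up to 0.0649%. Pdgfra was seen in 18.2% and 15.6% at this depth (0.717% and 0.541%) and in 63.6% and 70.2% without thinning, so no order was read from its shares. Differences in the shares for Acan (-0.0864 percentage points, interval -0.395 to 0.158) and Runx2 (0.885 points, -0.825 to 2.56) were not detectable at this depth.

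Of the 27 gene lists fixed before the data were examined, 26 had enough measured members, and each list's median log2 ratio was placed among 10000 random lists matched on size and expression; 6 lists lay above the central 95% of these and 8 below it. Inflammatory cytokines, chemokines and acute-phase genes had a median of 1.07 (percentile 99.87), with 10 of 16 measured members at least 1.5-fold higher and 5 at least 1.5-fold lower. The chemokine Ccl11 was 66.4-fold higher (0.232 and 15.4 CPM), at 61.9 CPM in cluster 10 and at 2.31 and 0.147 CPM in clusters 3 and 6, while the acute-phase gene Hp had a ratio of 0.0383 and the hyaluronan-binding gene Tnfaip6 0.192. The BMP pathway had a median of 0.80 (99.75; 9 of 16 higher and 2 lower), with the BMP antagonist Grem1 9.81-fold higher (46.7 and 458 CPM) beside Bmp2, and the BMP target Id3 at a ratio of 0.451. In the Notch pathway the median was 1.52 (99.59; 3 of 4 higher, none lower), with the target Hes1 4.77-fold and the transcription factor Rbpj 3.86-fold higher. YAP/TAZ targets and regulators had a median of 1.09 (99.91; 8 of 13 higher, 3 lower), Ctgf being 6.26-fold higher (26.6 and 167 CPM) and the tissue factor gene F3 at a ratio of 0.182.

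Secreted growth and angiogenic factors had a median of 0.88 (99.79; 10 of 16 higher, 3 lower), with Vegfa, the main angiogenic factor, 11.2-fold higher (8.46 and 94.9 CPM) and Fgf2 3.52-fold, although the mean of the list was -0.067 because of Ptn and Igf1. Mitochondrially encoded genes had a median of 1.78 (100; 10 of 13 higher, none lower), led by mt-Nd4l at 19.1-fold and mt-Nd3 at 6.49-fold. The lowest members, mt-Co3 and mt-Nd1, were 1.14-fold and 1.18-fold higher. The median mitochondrial share of UMIs, a measure of cell quality, sums the same genes and so is not separate evidence. It was 2.55% and 4.42% in mesenchymal-like, 2.89% and 4.13% in macrophage-like and 3.13% and 5.65% in osteoclast-like cells. In macrophage-like cells the medians were 1.16 for mitochondrially encoded genes (percentile 99.96), 1.60 for the Notch pathway (99.64) and 1.20 for the inflammatory list (97.535), on the same side of the random lists as in mesenchymal-like cells, and those of the BMP pathway, YAP/TAZ genes and secreted factors lay within the random lists. With no minimum level for members, the Notch median was 0.30 and lay inside the range of random lists. Without cycling cells the BMP median was 0.63 and also lay inside it, and with a mean in place of the median YAP/TAZ genes (0.59) did so too. Over all retained cells, the medians of BMP (0.58), YAP/TAZ (0.85) and secreted factor genes (0.67) lay inside that range as well.

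The lists below the random lists held matrix, contractile and differentiation genes. Collagens had a median of -1.0 (0; 8 of 15 lower, 3 higher), with Col1a1 at 1674 and 267 CPM (ratio 0.160) and Col12a1 at 0.192, while the basement membrane chains Col4a1 and Col4a2 were 6.96-fold and 3.24-fold higher. Matrix glycoproteins, proteoglycans and crosslinkers had a median of -0.88 (0; 15 of 25 lower, 3 higher), with Prelp at a ratio of 0.00346 beside Fmod, and the wound matrix gene Tnc 8.54-fold higher (48.9 and 417 CPM). Myofibroblast and contractile genes had a median of -0.90 (0.01; 8 of 14 lower, 1 higher), with the calponin gene Cnn1 at a ratio of 0.127, Lmod1 at 0.202 and Cald1 1.52-fold higher; without cycling cells the median was -0.16, inside the range of random lists. Tenogenic genes had a median of -3.36 (0; 3 of 4 lower, none higher), with the tendon regulator Scx at a ratio of 0.226 and Tnmd at 0.00818. With the libraries clustered apart, 142 uninjured cells (3.33%) formed a tenocyte-like cluster of their own, led by Ndufa4l2, Thbs4 and Comp, and in that setting the ratio of Ndufa4l2 was 0.0292 and the tenogenic list stayed below the random lists. Osteogenic genes had a median of -2.24 (0.01; 7 of 9 lower, 1 higher), with Ibsp at a ratio of 0.0423 beside Alpl, and Spp1, which encodes osteopontin, 9.85-fold higher (1805 and 17784 CPM). In 5 of 15 alternatives, all retained cells not being counted, a separate osteoblast-like cluster took these cells out of the uninjured class. The osteogenic median was then between -0.34 and -0.11, inside the range of random lists.

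Housekeeping lists with low medians were ribosomal protein genes (-0.39; percentile 0; 32 of 88 lower, 6 higher), with Rpl13a at a ratio of 0.277 and Rps21 2.68-fold higher, and oxidative phosphorylation genes (-0.36; 0; 20 of 88 lower, 2 higher), with Cox6a1 at 0.366 and Ndufs1 1.83-fold higher. Cholesterol synthesis genes had a median of -0.27 (1.67; 5 of 14 lower, 1 higher), with Fdps at a ratio of 0.273 and Mvd at 0.391; the median lay inside the range of random lists in male cells (-0.18) and with mixed clusters counted (-0.12), and was 0.28 over all retained cells.

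In macrophage-like cells ribosomal protein genes (-0.88) and oxidative phosphorylation genes (-0.67) lay below the random lists too, while matrix, osteogenic and cholesterol synthesis genes lay within them. Collagens (-1.27) and myofibroblast genes (-0.26) also lay below them there, but at levels near the background of mesenchymal transcripts, with Col1a1 at 52.7 and 10.01 CPM, Acta2 at 141 and 48.7 CPM and EGFP at 98.8 and 56.8 CPM, so these medians were not read as a difference in macrophage-like cells.

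The remaining 12 lists lay within the random lists. Stem and progenitor markers (median 0.26, percentile 73.8; 5 of 12 higher, 4 lower) held the intermediate filament gene Nes at 6.98-fold and Ly6c1 at a ratio of 0.117. Chondrogenic genes (0.90, 66.9; 2 of 3 higher, 1 lower) held Sox5 at 3.99-fold, adipogenic genes (-0.59, 2.67; 1 of 5 higher, 3 lower) Plin2 at 2.05-fold and Lpl at 0.447, and the TGF-beta pathway (0.51, 93.1; 9 of 19 higher, 4 lower) Skil at 2.98-fold and Tgfb2 at 0.299. The WNT pathway (-0.30, 3.61; 3 of 11 higher, 5 lower) held the antagonist Dkk2 at 9.41-fold and Sfrp1 at 0.276, and the Hedgehog pathway (0.05, 34.3; 2 of 5 higher, 1 lower) Gli3 at 1.67-fold and Gas1 at 0.229. Proteases and their inhibitors (0.09, 39.3; 7 of 21 higher, 5 lower) held the urokinase gene Plau at 18.8-fold beside Mmp3 and Adamts5 at 0.244, and hypoxia and glycolysis genes (-0.19, 10.4; 5 of 20 higher, 8 lower) Hk1 at 1.98-fold and Bnip3 at 0.356. Immediate early genes (0.35, 76.7; 7 of 16 higher, 3 lower) held Klf2 at 6.32-fold and Fos at 0.477, and heat shock and unfolded protein genes (-0.02, 42.9; 4 of 15 higher, 3 lower) Hspa1b at 11.3-fold and Trib3 at 0.0669. For p53 and senescence genes (0.22, 75.02; 4 of 14 higher, 1 lower) Mdm2 stood at 2.75-fold and Plk2 at 0.579, and for proliferation genes (0.17, 50.1; 6 of 30 higher, 3 lower) Kif11 at 2.43-fold and Cdc20 at 0.615. Of the interferon-response genes, the 2 measured members were Ifitm3 at 1475 and 1126 CPM and Bst2 at 14.9 and 8.01 CPM. Adipogenic genes lay below the random lists in 12 of 15 alternatives and WNT genes in 8, the setting of all retained cells not being counted. The TGF-beta pathway lay above them without cycling cells (0.70).

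**Figure D3:**
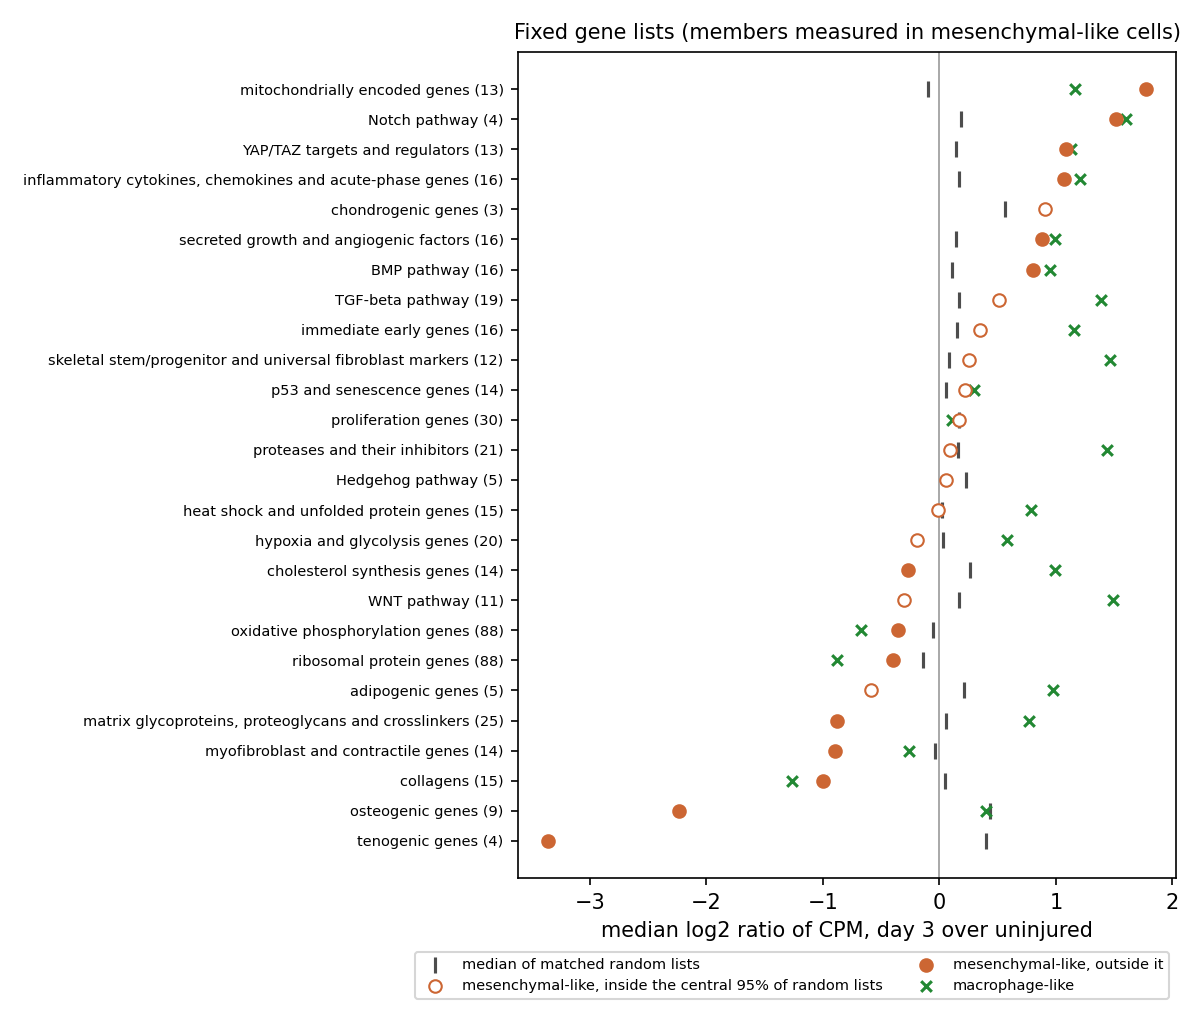
Median log2 ratio of CPM, day 3 over uninjured, of each fixed gene list in mesenchymal-like cells (circles, filled where outside the central 95% of random lists) and macrophage-like cells (crosses), with the median of matched random lists as a bar. In mesenchymal-like cells mitochondrially encoded genes lie at 1.78 and tenogenic genes at -3.36.

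A further comparison asked which cells the libraries held. Mesenchymal-like cells made up 49.1% of the uninjured library (exact 95% interval 47.6 to 50.6) and 23.1% of the day-3 library (22.4 to 23.8), and macrophage-like cells 27.2% (25.8 to 28.5) and 51.2% (50.3 to 52.1), or 26.2% and 39.5% without doublet removal. Neutrophil-like cells, which included cells rich in the granule genes Elane, Prtn3 and Mpo, were 0.258% of the uninjured library and 6.10% of the day-3 library. The name is less sure for the 261 day-3 cells of cluster 19. They held S100a8 at 7559 CPM, against 153750 and 131152 CPM in the neutrophil-like clusters 16 and 20. Their Ccr2 was at 526 CPM, against 1.29 and 6.21 CPM there and 756 CPM in the macrophage-like cluster 13. Dendritic-like cells with Cd74 and H2-Aa were 0.375% and 7.85%. The dendritic-like class depended on the settings, with 75 day-3 cells at up to 20% mitochondrial UMIs, 29 at a Leiden resolution of 2 and no cluster of that name without doublet removal. Osteoclast-like cells with Acp5 and Mmp9 were 5.86% (5.17 to 6.60) and 5.29% (4.90 to 5.69). They were 5.80% and 10.3% without doublet removal and 6.06% and 13.2% at up to 20% mitochondrial UMIs, so no order was read from these shares. Chondrocyte-like cells, a cluster led by Col2a1 with a Col2a1 UMI in 60 of its cells (36.6%), were 164 of 12580 cells at day 3, 1.30% (1.11 to 1.52), and 0 of 4268 in the uninjured library, which allows a share of up to 0.0703%. With filters of 300 genes and 500 UMIs, 815 day-3 cells (5.86%) and 3 uninjured cells took this name. A contractile cluster led by Tpm2, Tagln and Acta2 stayed unnamed, with 2.13% of uninjured and 1.70% of day-3 cells, and clusters with markers of several types held 15.1% and 3.45%. Shares depend on the cells that survived explant culture and on the minimum of 1000 UMIs, under which more of the shallower day-3 library was lost. The clusters that make up the mesenchymal-like and macrophage-like classes differed between the libraries, so shares are given for whole classes and not for single clusters.

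**Figure D4:**
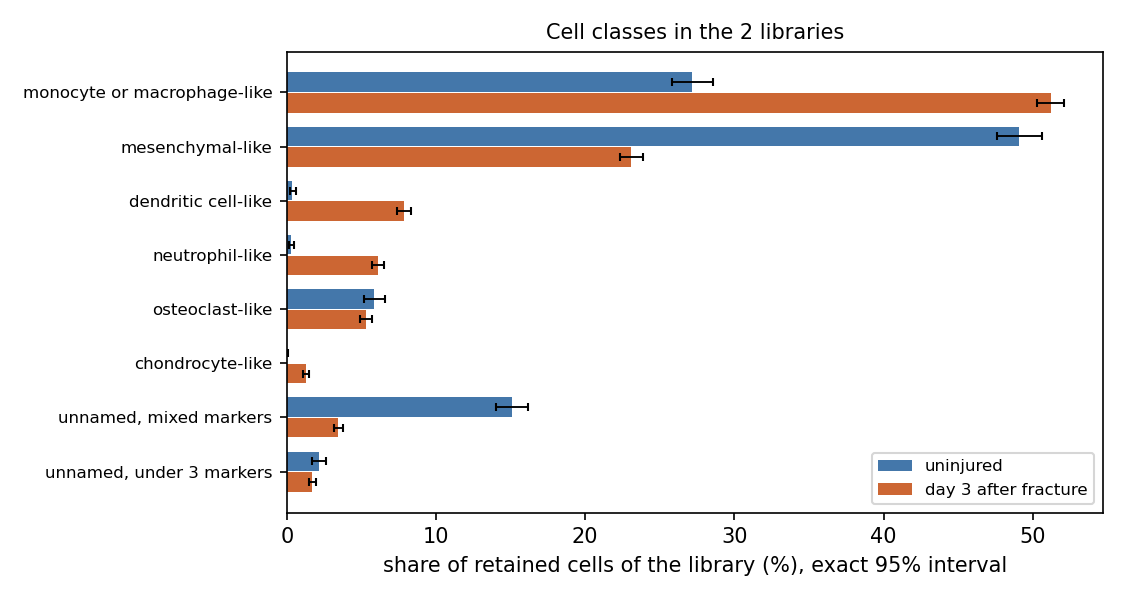
Share of retained cells in each class in the uninjured and the day-3 library, in percent, with exact 95% intervals. Macrophage-like cells were 27.2% of the uninjured and 51.2% of the day-3 library.

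The last comparison concerned proliferation of mesenchymal-like cells. With each cell thinned to 3000 UMIs, 29.6% of uninjured cells (27.6 to 31.6) and 35.8% of day-3 cells (34.0 to 37.6) had at least 3 UMIs over 15 mitotic genes such as Top2a, Cdk1 and Plk1. The summed level of these genes was 1081 CPM in the uninjured library and 1099 CPM at day 3, and Mki67, a marker of dividing cells, was 1.96-fold higher (35.5 and 69.6 CPM). The thinning left out 3 uninjured and 40 day-3 cells, and without thinning the shares were 67.3% and 76.0%. With at least 2 UMIs per cell the shares were 35.7% and 42.7%. With the libraries clustered apart they were 35.3% and 36.4%, and without doublet removal 34.4% and 36.2%. The difference was then 1.05 and 1.84 points, against 6.22 points in the main setting. It was 3.63 points with at most 20% mitochondrial UMIs and 3.72 points with the automatic Scrublet threshold. The size of the difference thus depended on the setting. No interval is given for these differences, so a higher share at day 3 was not read from these settings. Macrophage-like cells had shares of 39.8% and 24.2% by the same rule, over the 1116 of 1160 uninjured and 4623 of 6441 day-3 cells with at least 3000 UMIs.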

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

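The tests for the kit version as the whole cause, for sex and for dividing cells were set out before their results were seen; all other tests in this part were chosen after the pattern was seen.

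Genes at least 2-fold apart between the mesenchymal-like cells, such as Cebpb, Bmp2 and Fmod, were weighed against different 10x kit versions, since the libraries carried 480 and 960 distinct barcode starts of 7 bases with 129 shared. Of 440 such genes at a comparable level in macrophage-like cells, 85.9% differed the same way there by at least 1.5-fold. Another 57 differed by less and 5 the other way. A kit effect would give this and so would an injury response shared by both cell types. The rule for a comparable level also favours genes that differ the same way, so the percent is partly a product of selection. The labels name the same kit, so a change of kit version is inferred from the barcodes only. For 321 genes without a comparable level, such as Bmp2 and Fmod, such a change and injury cannot be told apart, because both would change with the library. Sex as the whole cause was excluded, since 95.7% of the genes stayed at least 2-fold apart the same way in male cells, and so was the share of dividing cells, since 95.5% did without cycling cells. The fracture, which is the biological difference in the design, may underlie the pattern in part or in whole and stays untested.

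Cells with both mesenchymal and macrophage transcripts made up 15.1% of the uninjured and 3.28% of the day-3 library. Doublets may account for part of them at day 3, where 21.8% of 413 mixed cells carried Xist and Y-linked UMIs together, against 6.06% of mesenchymal-like cells (5.22 to 6.99). Random pairs would lie below and above the median synthetic pair equally often in EGFP per mesenchymal marker UMI. Of the mixed cells 88.5% (uninjured) and 90.3% (day 3) lay below it, which argues against pairs drawn at random as the whole cause. The rule for this test also asked for mixed medians below the central 95% of such pairs. The medians of 0.134 and 0.25 lay within it (0.0650 to 1.86 and 0.149 to 2.02), so by that rule the test could not tell. That range is the spread of single pairs, not the error of a median, and random pairs as part of the cause stay open. Mixed cells had median depths of 23038 and 17543 UMIs, against 35692.5 and 39800 in the pairs. Free RNA stays open by the rule set for it. In the uninjured library osteoclast markers were 20.0-fold and macrophage markers 17.8-fold above their level in mesenchymal-like cells (1.12-fold apart), as a common source would give. At day 3 they were 3.97-fold and 15.3-fold above it, and neutrophil markers, which the rule did not use, 1.48-fold. Such a spread is not what free RNA alone would give at day 3. This takes the level in mesenchymal-like cells as background, which was not tested. Neutrophil markers were 1.49-fold above it in the uninjured library, where neutrophil-like cells were few. Doublets in the male uninjured library could not be tested by sex and stay open, with a median Scrublet score of 0.0819 in mixed cells against 0.0311 in mesenchymal-like and 0.0252 in macrophage-like cells, and uptake of one cell type by another was not tested.

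Of the genes at a comparable level, 5 were lower at day 3 in mesenchymal-like cells and higher in macrophage-like cells, a difference that was not tested. The log2 ratios were -2.06 and 0.93 for the glutathione transferase gene Gstm1, -1.06 and 1.11 for the immediate early gene Junb, -1.14 and 0.85 for the lactate transporter gene Slc16a3, -1.77 and 1.17 for the membrane glycoprotein gene Emb, and -1.11 and 1.29 for the RNA-binding protein gene Zfp36l1. In osteoclast-like cells the ratio was 2.18 for Emb and 2.30 for Zfp36l1, as in macrophage-like cells. It was 0.512 for Slc16a3, as in mesenchymal-like cells, 0.872 for Gstm1 and 0.962 for Junb. Genes without a comparable level are not in this count. Among them, Il1rn had log2 ratios of -5.46 in mesenchymal-like and 1.26 in macrophage-like cells. The unrecombined reporter tdTomato, which enters no comparison, was at 2.16 CPM in uninjured and 3.80 CPM in day-3 macrophage-like cells, against 0.0893 and 0.00905 CPM in mesenchymal-like cells. Xist was at 365 CPM over all retained day-3 cells and 0.0905 CPM over all retained uninjured cells, and 17.3% of the sexed day-3 mesenchymal-like cells (15.9 to 18.8) carried Y-linked UMIs alone.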

How the results depend on the processing

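Tests of male cells only, of mixed clusters counted as mesenchymal-like, of all clusters rich in EGFP and of the lower filters were chosen after the data were seen; all other settings were fixed before. No paired analysis was possible because there was 1 library per group, and for the same reason no library could be left out. The counts of genes at least 2-fold higher and lower stayed within 1.5 times of 542 and 220 under 14 of 15 alternatives, between 494 and 661 and between 190 and 303. Of the list medians recomputed, 379 kept their place inside the random lists or outside them on the same side, 21 moved outside, 14 moved inside and 2 that lay outside changed sign. The 30 named genes kept a 2-fold difference on the same side in each alternative run on them, Xist in male cells aside. With a minimum of 10 CPM, which admits more genes by construction, 1411 and 522 genes passed. Separate osteoblast-like clusters explain the osteogenic medians and the Sp7 values below by construction; for all other values below that changed, the cause was not tested. With at most 5% mitochondrial UMIs, medians were -0.32 for osteogenic, -0.75 for adipogenic and -0.44 for WNT genes, mesenchymal-like shares 43.1% (uninjured) and 25.3% (day 3), and cycling shares 32.6% and 39.0%. With at most 20%, they were -0.12, -0.76 and -0.42, the uninjured share 41.5%, the cycling shares 32.4% and 36.01%, the Sp7 log2 ratio 0.041 and its difference in shares 0.221 points. Without doublet removal, the same medians were -0.34, -0.83 and -0.41, the mesenchymal-like shares 40.9% and 20.2% and the cycling shares 34.4% and 36.2%. With Scrublet's automatic threshold, they were -0.34, -0.83 and -0.40, then 41.1%, 20.1%, 32.7% and 36.4%, with 0.0724 points for Sp7. With libraries clustered apart, they were -0.11, -0.75 and -0.39, the uninjured share 38.6%, the cycling shares 35.3% and 36.4%, the Sp7 log2 ratio 0.036 and its difference 0.286 points. Without cycling cells, medians were -0.16 for myofibroblast, -0.68 for adipogenic, 0.63 for BMP, 0.70 for TGF-beta and -0.98 for WNT genes, and log2 ratios -0.65 for Kif11 and -0.56 for Mki67, genes by which cycling cells were defined or which they carry. Over all retained cells, medians were 0.58 for BMP, 0.85 for YAP/TAZ, 0.67 for secreted factor and 0.28 for cholesterol genes, and log2 ratios 0.55 for Lpl, 0.27 for Hp, 0.64 for Fos and 2.12 for Acan. With all clusters rich in EGFP, which add the chondrocyte-like cells, Acan had 2.39. Adipogenic medians were -0.65 with TMM, -0.71 with cells thinned to 3000 UMIs, -0.72 with cells weighted equally (WNT -0.75), -0.77 in male cells (cholesterol -0.18), -0.81 with no minimum for members (Notch 0.30) and -1.03 with mixed clusters counted (WNT -0.31, cholesterol -0.12, shares 64.2% and 26.4%). Means over members were 0.59 for YAP/TAZ and -0.067 for secreted factors. The day-3 share was 21.0% with filters of 300 genes and 500 UMIs. Cycling shares were 35.7% and 42.7% with at least 2 mitotic UMIs, 67.3% and 76.0% without thinning and 24.7% and 28.4% at 2000 UMIs, higher at day 3 in each; Pdgfra shares differed by 6.52 points without thinning. TMM moved log2 ratios by -0.061. Depth limited Acan, with 28 and 27 UMIs, and Runx2, whose shares could not be told from each other at 3000 UMIs.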

Other observations

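All tests in this part were chosen after the pattern was seen. Macrophage-like cells also differed between the libraries. Among 3675 genes at 50 CPM or more, 1145 were at least 2-fold higher at day 3 and 235 at least 2-fold lower, with a median log2 ratio of 0.62 over all genes at 10 CPM or more. Arg1, an arginase of wound macrophages, was 61.6-fold higher at day 3 (3.13 and 193 CPM), the chemokine Cxcl3 55.3-fold (1.52 and 84.2 CPM), the monocyte antigen Ly6c2 31.7-fold (805 CPM in the 529 cells of cluster 13 and 10.9 CPM in cluster 0, the largest of the class), Cebpb 30.5-fold (25.3 and 773 CPM) and the matricellular gene Thbs1 19.3-fold (28.3 and 547 CPM). The chitinase-like gene Chil3 was 334-fold higher (92.2 to 2757; 2 UMIs in the uninjured library), at 430 CPM in cluster 13 and 16.4 CPM in cluster 0, against 811 to 6054 CPM in the neutrophil-like clusters. S100a9 and S100a8 were 88.3-fold and 26.6-fold higher in the same macrophage-like cells. They were at 1314 and 3948 CPM in cluster 13 and at 141 and 165 CPM in cluster 0. Free RNA from neutrophil-like cells was not separated from the macrophage-like cells' own transcripts. Rnaset2a had a ratio of 0.169 and the interferon-inducible gene Ifi27l2a 0.243 (401 and 97.3 CPM). Proteases and their inhibitors had a median log2 ratio of 1.44 (percentile 99.91), the TGF-beta pathway 1.39 (99.75) and immediate early genes 1.15 (99.64), lists that lay within the random lists in mesenchymal-like cells, a difference between classes that was not tested. Osteoclast-like cells lay in different clusters by library, 235 of 250 uninjured cells in cluster 18 and 623 of 665 day-3 cells in cluster 12, with Acp5 at 1050 and 4057 CPM. In the whole class 581 genes were at least 2-fold higher at day 3 and 113 lower, with the transcription factor Jdp2, which acts in osteoclast formation, 13.6-fold higher (28.8 and 392 CPM) and the neuropeptide gene Npy at a ratio of 0.135 (117 and 15.7 CPM).

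Day-3 mesenchymal-like cells fell into clusters with different genes. Cluster 10 held Mmp3 at 453 CPM, the alarmin Il33 at 339 CPM, the chemokines Ccl2 and Ccl7 at 1483 and 949 CPM and the retinoid-binding gene Crabp1 at 1372 CPM. Cluster 6 held Serpinb2 at 645 CPM, Gzme at 223 CPM and Spp1 at 25556 CPM, and cluster 3 held the dividing cells, with Mki67 at 164 CPM and Top2a at 317 CPM. The unnamed contractile cluster held Acta2 at 4888 CPM in uninjured and 1683 CPM in day-3 cells, with EGFP at 2790 and 2195 CPM. Its day-3 cells held Xist at 10.0 CPM, against 324 CPM in day-3 mesenchymal-like cells. Of these 214 day-3 cells, 169 carried neither Xist nor Y-linked UMIs, against 104 of 2906 mesenchymal-like cells. The reason was not tested.

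The day-3 library held 164 chondrocyte-like cells with a median of 1169.5 UMIs, of which 60 (36.6%) had a Col2a1 UMI. Summed over the cluster, Col2a1 was at 3275 CPM and Acan at 1263 CPM, beside Col1a1 at 12026 CPM, Postn at 2617 CPM and EGFP at 1992 CPM, and the stress-responsive genes Fos and Fosb at 2612 and 829 CPM, against 5.49 and 3.30 CPM in day-3 mesenchymal-like cells. Of the 705 day-3 cells of any class under 1500 UMIs, 31 held at least 10 chondrocyte marker UMIs. An even spread of these UMIs by depth would give 0.000773 cells, so evenly spread free RNA is not the whole cause. The cluster had been named from the same markers, so a high count was likely beforehand. Free RNA that is unevenly spread over droplets was not tested. Whether the cells came from the same mix of animals as the mesenchymal-like cells stays open, since 0 of 67 sexed cells carried Y-linked UMIs alone (upper bound 5.36%), but the measure differs between classes of the same animals, at 8.89% of mesenchymal-like (7.02 to 11.1) and 13.1% of macrophage-like cells (11.7 to 14.6) at the same depth. Whether they arose after the fracture or from nearby cartilage was not tested.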
